A study of Mus musculus with 2 samples.

How the data were processed

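DNase-seq libraries of left cerebral cortex from 2 biological replicates of male B6CASTF1/J mice at 14 days were used; the labels gave 1 group, separate biosamples and no batch. Both labels carry the same donor identifier, which may stand for the strain; if it does not, the SD over libraries is not a spread between animals. For each library the deposited files held a more inclusive and a stricter peak list, footprints, and intervals with the false discovery rate of the local cleavage rate. Per the file headers and notes, each file was made by the authors from that library's own mm10 alignments, and replicates were not pooled. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here.

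Peak signal is the authors' deposited value per peak, the highest cleavage density in the peak as scaled by the authors to sequencing depth; the score, p and q columns of the peak lists carried no values. Signals in the lower range, the only ones checked, were whole multiples of 0.00474 in replicate 1 and 0.00614 in replicate 2. Each lay within 0.05 of a step, and the ratio of steps was 1.30. The deposited interval file gives a q-value (false discovery rate) per interval and lists only intervals up to 0.05; these covered 43.1 Mb and 42.9 Mb. Checked against these intervals, every peak of the inclusive list had a best value under 0.05 and every peak of the stricter list (89013 and 92506 peaks) under 0.001. The inclusive list was used throughout and the stricter one as an alternative. The score column of the footprint files held the same value throughout and was not used.

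Gene models were GENCODE M21 and the sequence was GRCm38, the assembly that mm10 names, on 21 chromosomes (1 to 19, X and Y). A promoter peak lay within 1000 bp of any annotated transcription start, and the promoter signal of a gene was that of its strongest such peak. Peaks were placed by their centre in promoter, exon, intron or intergenic sequence, in that order. Gene lists (23, with 352 symbols, all found, 5 of them not protein-coding and 1 in more than 1 list) and 27 consensus words were fixed before the data were examined, as were the tests and all alternatives. The olfactory and vomeronasal receptor families, by symbol, made 2 further lists.

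Peaks were compared between libraries by overlap of at least 1 bp, with 100 seeded circular shifts as the chance level. Promoter lists were tested in each library by a two-sided Fisher's exact test against all other protein-coding genes. Gene body counts were tested by a two-sided permutation test against 10000 random lists matched on gene length in 20 bins (1000 lists for families over 400 genes). Words were matched on either strand in footprints extended by 5 bp and in windows of the same width from the same peak outside footprints, 286804 and 288853 pairs, by a two-sided Fisher's exact test. All p-values were adjusted by Benjamini-Hochberg within a library, and a call needed an adjusted p under 0.05 in the same direction in both libraries. Genes and windows within a library are not replicates, so these tests do not extend to other animals. Ratios between libraries were described by percentiles among 10000 random lists matched on mean signal in 20 bins, for lists with at least 3 genes open in both.

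Some genes that the rule takes, and 1 word, are not reported here but count in the totals. Genes were named by a rule: per list the 3 with the highest mean promoter signal and up to 2 without a promoter peak in alphabetical order, the 10 protein-coding genes with the most peaks, the 10 distal peaks with the highest mean rank, and the 5 genes with the largest promoter ratio in each direction among those above the median signal. The count of genomic copies of 31-base words in distal peaks, the marking of promoter peaks that also lie at another gene's start, and the motif matches in single promoters were added after the values were seen.

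Peak sharing, peak signal, promoter lists, gene body lists, ratio lists and words were tested on simulated data. Of 150726 simulated peaks 69.9% were kept and 70.6% were found shared, and a ratio SD of 0.4 was returned as 0.401. Among 21911 genes, promoter list tests passed an unadjusted 0.05 in 0.5% of unchanged lists and 98.5% of lists with 20% open promoters. Open promoters were simulated without regard to CpG count, so these rates do not cover lists that differ in it. Gene body tests did so in 1% of unchanged lists and 89% of lists with 3 times the counts, and ratio lists left the central 95% in 3% of unchanged lists and in 100% of lists moved by 0.5. A CTCF word placed in 5.03% of 20000 windows was found in 5.03% of them and in 0.005% of controls.

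Alternatives were the overlap, the peak list and height, the promoter window, the transcription starts, CpG-matched lists, the flank, the centring, the footprint extension, matched controls and each library alone. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.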

Results

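Accessible chromatin was mapped by DNase-seq, in which the nuclease DNase I cleaves DNA that is not packed into nucleosomes, in the left cerebral cortex of male mice at 14 days of age. The animals were B6CASTF1/J, the first-generation hybrid of the C57BL/6J and CAST/EiJ strains. The design held 1 group with 2 biological replicates; the label of replicate 1 named 3 males and that of replicate 2 named 1 male. No second condition was present, so the comparisons are between the libraries, between gene groups within each library, and between parts of the genome. Values are means ± SD over n = 2 libraries unless a library is named, and coordinates are in mm10.

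Replicate 1 held 150726 peaks and replicate 2 held 155536 (153131 ± 3401), with a median width of 180 bp in both. Peaks covered 1.06% of the genome on average. The authors called 380111 footprints, the short protected stretches that bound proteins leave inside accessible DNA, in replicate 1 and 379156 in replicate 2. Sequencing depth was not given in the sources used here. Peak heights in the lower range, which was checked and includes the median peak, were whole multiples of a step in each library. The median peak stood at 116 steps in replicate 1 and 108 in replicate 2. That gives a counting error of 9.28% and 9.62% for a single peak if a step is 1 read.

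Most accessible sites of the cortex were found in both libraries. Of the peaks of replicate 1, 78.7% overlapped a peak of replicate 2 by at least 1 bp (Wilson 95% interval 78.5 to 78.9), and 76.3% did so in the other direction (76.1 to 76.5), a mean of 77.5% ± 1.67. After 100 circular shifts of a peak set along each chromosome the shares were 2.22% and 2.15%. Among the strongest 10% of peaks 99.7% were shared in either library, and among the weakest 10% the shares were 36.7% and 33.3%. Promoter peaks were shared more often (83.7% ± 0.744) than intronic (75.9% ± 2.43), intergenic (75.2% ± 2.59) or exonic peaks (72.4% ± 1.17). The 32133 peaks listed for replicate 1 alone had a median signal of 0.322, against 0.677 for its shared peaks, and the 36822 listed for replicate 2 alone had 0.375, against 0.835. Of these private peaks, 14.5% and 17.7% lay in intervals that passed the false discovery rate limit in the other library. Across the 118593 shared sites, which are not replicates, Pearson's r of log10 signal was 0.942 and Spearman's rho 0.920. The log2 ratio between libraries had an SD of 0.43, compared with 0.19 from counting error alone if a step is 1 read. Intervals cover counting error only.

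Promoters held 25.7% ± 0.735 of the peaks in 5.88% of the genome, a 4.38-fold excess, and their peaks were the strongest, with a median signal of 0.843 in replicate 1 and 0.977 in replicate 2. Exons held 4.55% ± 0.0406 of peaks (3.09% of the genome) and introns 36.3% ± 0.364 (37.3%). Intergenic DNA held 33.5% ± 0.411 of peaks in 53.7% of the genome, 0.623 of its share, with the lowest median signal, 0.455 and 0.541. The promoter excess of 4.38-fold was far larger than the spread between the libraries.

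Among peaks over 2000 bp from any transcription start, the top-ranked site lay on chromosome X at 143482981 to 143483140, intergenic and nearest to Pak3, a kinase of dendritic spines, with a signal of 26.2 ± 9.68. A site on chromosome 15 from 99735661 to 99736060, in annotated exon sequence within the ceramide synthase gene Cers5, reached 22.0 ± 4.64. The site on chromosome 9 from 123461921 to 123462100, in exon sequence within the mitochondrial leucyl-tRNA synthetase gene Lars2, reached 25.1 ± 9.31. Exons of all gene types counted, so an exon need not belong to the gene named. An intergenic site on chromosome 8 from 126666541 to 126666760, nearest to Irf2bp2, had 16.4 ± 3.05, and another on chromosome 6 from 49236441 to 49236620, nearest to the RNA-binding protein gene Igf2bp3, had 21.4 ± 6.05. An intron of Igf1r, the receptor of an insulin-like growth factor, carried a peak of 14.0 ± 2.75 on chromosome 7 from 68129121 to 68129260. The other 4 sites lay nearest to Cstad (15.9 ± 2.35) and Tle2 (14.0 ± 3.69), in exon sequence within C87436 (14.5 ± 0.540), and in an intron of Mid1 nearest to Gm21887 (20.9 ± 13.4). Part of these sites held repeated sequence: of their 31-base words, 100% had several genomic copies at the Mid1 site, 88.7% at the site near Igf2bp3, 65.3% in Lars2 and 28.5% near Pak3, and 0% at the remaining 6. Mostly multicopy sites made up 3 of these 10 and 6 of the strongest 100 distal peaks, against 3 of 500 random distal peaks.

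Pan-neuronal, excitatory neuron, astrocyte and general cell genes had open promoters in this tissue. All 16 pan-neuronal, 20 excitatory neuron, 16 astrocyte, 12 oligodendrocyte precursor, 16 activity-regulated, 16 housekeeping and 16 chromatin and transcription machinery genes had a peak within 1000 bp of an annotated transcription start in both libraries. Of all 21911 protein-coding genes, 68.4% ± 0.413 had such a peak in a given library; 14609 (66.7%) were open in both libraries, 762 in 1 library and 6540 in neither. Cortical progenitor genes were open at 16 and 15 of 16 promoters. Fisher's exact test (two-sided, adjusted over 25 lists by Benjamini-Hochberg) placed these 8 lists above the other protein-coding genes in both libraries. The adjusted p was 0.00347 and 0.00352 for the excitatory list and 0.00913 and 0.00486 for each list open at 16 of 16 in both libraries. For oligodendrocyte precursors it was 0.0368 and 0.0198, and for cortical progenitors 0.00913 and 0.0389. When the comparison was with random lists matched on promoter CpG count, the calls of the housekeeping, activity-regulated, oligodendrocyte precursor and cortical progenitor lists ended, and those of the pan-neuronal, excitatory, astrocyte and chromatin machinery lists did not, with an excess of 18.8, 20, 28.1 and 12.5 percentage points in place of 31.6 for each. The excitatory and chromatin machinery calls ended with only the 5' end of each gene, the astrocyte call with the stronger 50% of the peaks, and the precursor and progenitor calls with either of these or a window of 2500 bp, the latter also with 500 bp. In these settings the precursor excess was 21.2 to 28.0 percentage points in place of 31.6, and the progenitor excess 19.1 to 27.3 in place of 28.5.

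**Figure D1:**
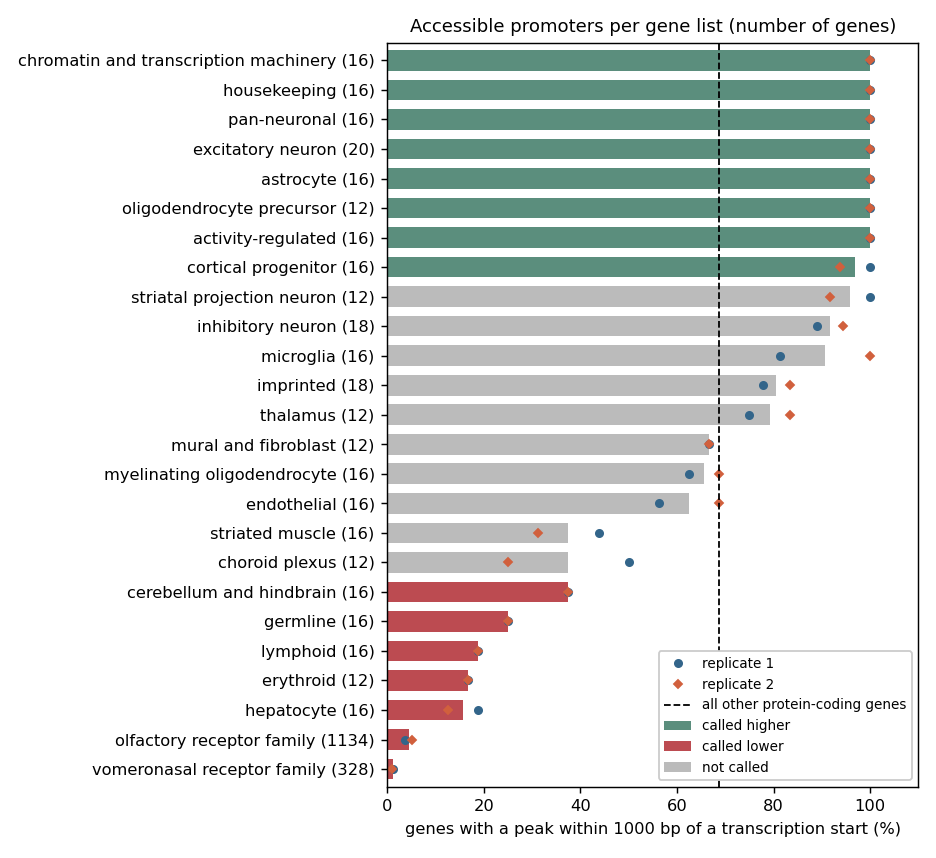
Share of genes with a peak within 1000 bp of a transcription start (x axis, percent) for each of the 25 gene lists (y axis, with the number of genes); bars show the mean of the libraries, circles replicate 1, diamonds replicate 2, and the dashed line all other protein-coding genes. The pan-neuronal, excitatory neuron, astrocyte and housekeeping lists reached 100%, the inhibitory neuron list had a mean of 91.7%, and the olfactory and vomeronasal receptor families lay at 4.41% and 1.07%.

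The strongest promoter peaks of the open lists differed in height. Housekeeping promoters had a median signal of 7.19 and 8.95 in replicates 1 and 2, chromatin machinery promoters 6.50 and 7.42, and activity-regulated promoters 5.61 and 7.08, compared with 3.47 and 3.91 for all protein-coding genes with a promoter peak. The medians were lower for pan-neuronal (3.05 and 3.18), excitatory neuron (1.88 and 2.36), oligodendrocyte precursor (1.28 and 1.44) and astrocyte promoters (1.14 and 1.66). Rplp0, a protein of the large ribosomal subunit, had 14.9 ± 0.0923, and the signalling adaptor Ywhaz and the prolyl isomerase Ppia had 11.5 ± 2.76 and 9.79 ± 0.592. Jun, a component of the AP-1 transcription factor, had 14.8 ± 3.54 at a peak that started at position 95052201 of chromosome 4 in replicate 1. The immediate early gene Egr1 had 8.81 ± 0.114, although the strongest peak was a different one in each library, and the synaptic scaffold gene Homer1 had 8.52 ± 1.99. Smarca4, the ATPase of the BAF remodelling complex, and the cohesin subunit Smc3 had 14.1 ± 2.97 and 11.4 ± 0.990. Among pan-neuronal genes the highest were the synaptic calcium sensor Syt1 (5.63 ± 1.58) and the neuronal tubulin Tubb3 (5.44 ± 0.964).

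Excitatory neuron promoters were led by Nrgn, which encodes a calmodulin-binding postsynaptic protein (5.00 ± 1.78), and the kinase Camk2a (4.71 ± 1.52). Inhibitory neuron genes were open at 16 and 17 of 18 promoters and were not called, with an adjusted p of 0.105 in replicate 1 and 0.0270 in replicate 2 by Fisher's exact test. The calcium-binding protein gene Calb2 had 2.36 ± 0.533 and Adarb2 2.17 ± 0.0721, and no promoter peak was listed for Sst, which encodes the neuropeptide somatostatin. In astrocyte genes the signal was 6.27 ± 1.62 at Id4, 6.27 ± 0.730 at the glutamine synthetase gene Glul, whose peak also lay at a start of Teddm2, and 3.40 ± 0.923 at the transcription factor gene Sox9. Oligodendrocyte precursor genes were led by values of 2.59 ± 0.337 at the proteoglycan gene Vcan, 2.39 ± 0.145 at Sox6 and 2.23 ± 0.703 at Olig1. Cortical progenitor genes included the topoisomerase Top2a (6.88 ± 0.811), the Notch target Hes1 (4.38 ± 0.891) and Lhx2 (3.86 ± 0.154).

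Myelin, microglial and vascular lists did not pass the test in both libraries. Myelinating oligodendrocyte genes were open at 10 and 11 of 16 promoters, with 1.35 ± 0.0497 at Cnp, a myelin enzyme gene, and 1.31 ± 0.112 at Fa2h; none was listed for the myelin genes Mag and Ermn. Microglial genes were open at 13 and 16 of 16 promoters (adjusted p 0.499 and 0.00486, Fisher's exact test; called higher against CpG-matched lists), with 1.73 ± 0.499 at the complement gene C1qc and 1.55 ± 0.0524 at Sall1. Endothelial genes were open at 9 and 11 of 16, led by the glucose transporter gene Slc2a1 (3.87 ± 1.03), Egfl7 (1.2 ± 0.117) and Erg (0.704 ± 0.0754). The Egfl7 peak also lay at a start of Gm20532, and no peak was listed at the tight junction gene Cldn5 or at Emcn. Mural and fibroblast genes were open at 8 of 12 in each library, with 3.40 ± 0.175 at the collagen gene Col1a1, from different peaks in each library, 1.30 ± 0.147 at Tagln and 0.824 ± 0.234 at Rgs5, and none at Col1a2 or Lum. None of these 4 lists was called, although the endothelial list was called lower with the stronger 50% of the peaks, nor was the imprinted list, open at 14 and 15 of 18. Within it, Kcnq1ot1 had 6.50 ± 0.507, Peg3 6.4 ± 2.08, at a peak shared with a start of Usp29, and Impact 6.14 ± 2.56, and no peak was listed at Igf2 or Ndn.

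Genes of neighbouring brain regions were mixed. Striatal projection neuron genes were open at 12 and 11 of 12 promoters, with 4.80 ± 0.284 at the G-protein regulator Rgs9 and 2.45 ± 0.30 at the dopamine receptor gene Drd1. Thalamic genes were open at 9 and 10 of 12, with 2.01 ± 0.118 at the nuclear receptor gene Rora, 1.85 ± 0.334 at Tcf7l2 and 1.70 ± 0.379 at Calb1, and without a peak at Lhx9 or Zic1. Choroid plexus genes were open at 6 and 3 of 12: Prlr had 1.64 ± 0.115, the water channel gene Aqp1 0.484 ± 0.0280, and Kl 0.725 in replicate 1 with none listed in replicate 2, and Calml4 and Folr1 had none. These 3 lists were not called, although the choroid plexus list was called lower with the stronger 50% of the peaks; by Fisher's exact test the adjusted p was 0.0368 and 0.149 for the striatal list and 0.277 and 0.00486 for the choroid plexus list. Cerebellum and hindbrain genes were open at 6 of 16 in each library and were called lower (Fisher's exact test, adjusted p 0.0220 and 0.0199). That call ended with a promoter window of 2500 bp and with the 5' end only, at differences of -25.5 and -29.3 percentage points in place of -30.9. Cbln1 had 3.87 ± 0.561, Cbln3 2.18 ± 0.180, at a peak shared with a start of Khnyn, and En2 0.519 ± 0.0564, and no peak was listed at Barhl1 or at the granule cell receptor gene Gabra6.

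Promoters of other tissues were mostly closed. Hepatocyte genes were open at 3 and 2 of 16 promoters, germline genes at 4 of 16 in each library, erythroid genes at 2 of 12 and lymphoid genes at 3 of 16. All 4 lists were called lower by Fisher's exact test, with adjusted p-values of 0.000344 and 5.49e-05, 0.00171 and 0.00208, 0.00152 and 0.00180, and 0.000344 and 0.000427. The hepatocyte, erythroid and lymphoid calls ended against random lists matched on CpG count, and the germline call did not. Olfactory receptors, the odorant receptors of the nasal epithelium, were open at 42 and 58 of 1134 promoters and vomeronasal receptors at 4 and 3 of 328 (adjusted p 2.27e-157 and 5.57e-157 for the latter by Fisher's exact test). Against lists matched on CpG count both families stayed called lower, with differences of -10.2 and -10.8 percentage points in place of -67.5 and -68.4. Striated muscle genes, open at 7 and 5 of 16, had an adjusted p of 0.0795 and 0.00808 by the same exact test and were not called, but were called lower with a window of 500 bp, with the 5' end only and with the stronger 50% of the peaks.

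Several of the open promoters in these lists belonged to windows with other gene starts. The strongest peak counted for Gdf9, an oocyte growth factor gene, had 11.8 ± 3.53 and also lay at a start of Uqcrq. That of Apoh, a plasma glycoprotein gene, had 6.85 ± 0.0631 and lay at a start of Prkca, and that of Vmn1r4 had 5.43 ± 0.966 and lay at a start of Nt5c3. With no other protein-coding start in the window, Apob had 2.39 ± 0.284, Dazl 2.03 ± 0.319, Tex15 0.838 ± 0.221, the erythropoietin receptor gene Epor 1.92 ± 0.0605, the T-cell kinase gene Lck 2.26 ± 0.111 and Pax5 1.30 ± 0.170. The muscle creatine kinase gene Ckm had 2.14 ± 0.962, Des 1.58 ± 0.273 and Myh7 1.25 ± 0.368. Olfr459, Olfr1414 and Olfr317 had 2.68 ± 1.39, 1.38 ± 0.321 and 1.38 ± 0.604, and Vmn1r27 and Vmn1r20 had 0.418 ± 0.0425 and 0.389 ± 0.0144. The serum albumin gene Alb had 0.275 in replicate 1 with none listed in replicate 2, and Cd2 had 0.565 in replicate 2 with none in replicate 1. No promoter peak was listed at Ahsg, Ambp, Acta1, Actc1, Ddx4, Figla, Alas2, Gata1, Cd3d, Olfr1, Olfr10, Vmn1r1 or Vmn1r10.

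Excitatory neuron genes also carried the most peaks in and around the gene body. Their median was 15 and 19 peaks in the gene body plus 10 kb on each side, compared with 7 in random lists of the same size matched on gene length (permutation test, adjusted p 0.00333 and 0.00167). Activity-regulated genes had 10 and 10.5 peaks against 3.5 and 3 (adjusted p 0.00250 and 0.00167, permutation test), with the smallest raw p that 10000 lists can give, 0.0002, in both libraries. Housekeeping genes had 7.5 and 6.5 against 3.5 (adjusted p 0.00375 and 0.0370, permutation test). Both receptor families had a median of 0 against 3 and were called lower. The other 20 lists were not called, among them the pan-neuronal list at 11.5 and 11 against 7.5 and the astrocyte list at 8.5 and 6 against 5. The excitatory call ended with a flank of 50 kb and with the stronger 50% of the peaks only, where the pan-neuronal list was called higher, and the housekeeping call ended with no flank, with 50 kb, and without peaks near transcription starts.

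The protein-coding gene models with the most peaks were long ones. Gm20388, a read-through model from 119910841 to 124345722 on chromosome 8 that spans many other genes, held 613 and 600 peaks. The growth factor receptor gene Fgfr2, annotated from 130162451 to 133123350 on chromosome 7, held 285 and 276. Its model also overlaps Ctbp2, so these peaks cannot all be assigned to Fgfr2. Gm37240, annotated from 84496426 to 85887518 on chromosome 3, held 164 and 120. Genes expressed in neurons followed: the splicing regulator Rbfox1 held 115 and 123 peaks, Camta1 104 and 107, the postsynaptic scaffold gene Dlg2 102 and 105, the acid-sensing channel gene Asic2 100 and 103, Nav2 93 and 105, Auts2 96 and 99, and Csmd1 91 and 99. The median protein-coding gene held 4 peaks in either library. At Nrgn 6 peaks were listed in replicate 1 and 31 in replicate 2, and at Lhx2 20 and 3.

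Inhibitory neuron promoters stood higher in replicate 1 and excitatory neuron and astrocyte promoters lower. The median log2 ratio of promoter signal, replicate 1 over replicate 2, centred on all 14609 genes open in both libraries, was 0.52 for 16 inhibitory neuron genes (SD between genes 0.26). It was -0.21 for 20 excitatory neuron genes (SD 0.32), -0.18 for 16 astrocyte genes (SD 0.37) and -0.05 for 37 olfactory receptors (SD 0.45). Among 10000 random lists matched on signal these medians lay at percentiles 100, 0.03, 0.62 and 0.97; random lists had medians of 0.13, 0.10, 0.09 and 0.14. Calb2 and Adarb2 had ratios of 0.69 and 0.16, and Nrgn and Camk2a had -0.52 and -0.44. The other 18 of the 22 lists with enough genes lay inside the central 95%, including striatal projection neuron genes (0.36, percentile 97.3, and 97.9, outside, with a promoter window of 2500 bp), endothelial genes (0.35), housekeeping genes (-0.17) and microglial genes (-0.01). With 1 library on each side there is no test, and the values describe these libraries. Centred on the housekeeping list, the excitatory median was -0.04, the astrocyte median -0.01 and the olfactory median 0.12; with sums over gene body peaks only the inhibitory list stayed outside and the astrocyte and olfactory medians turned to 0.05 and 0.08.

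**Figure D2:**
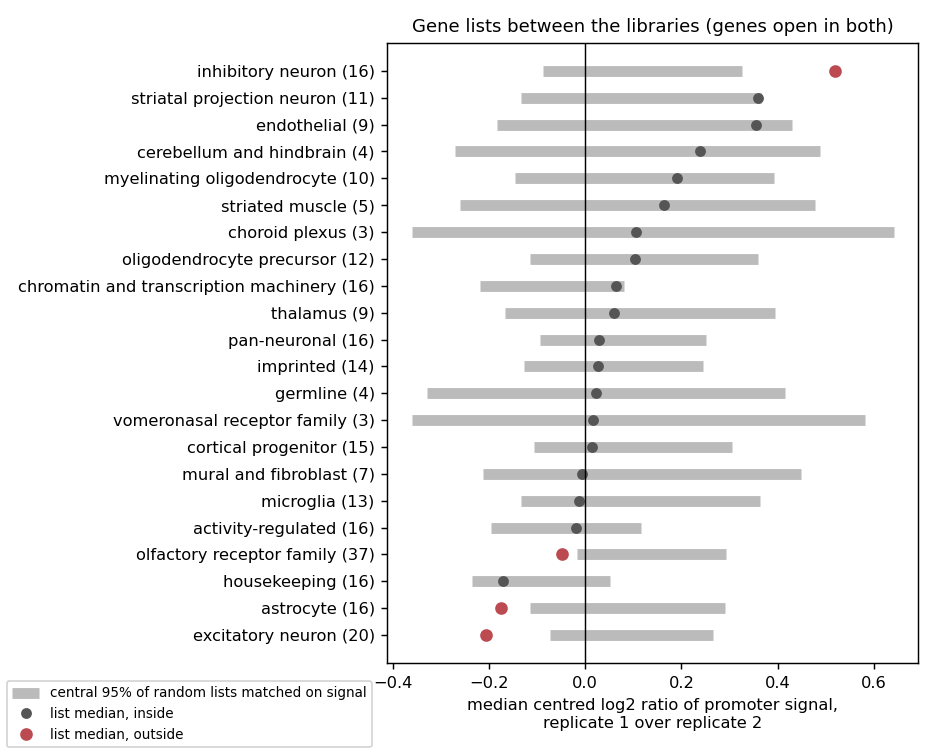
Median centred log2 ratio of promoter signal, replicate 1 over replicate 2 (x axis), for the genes of each list that were open in both libraries (y axis, with their number); grey bars show the central 95% of random lists matched on signal. The inhibitory neuron list at 0.52 lay above its bar, and the excitatory neuron, astrocyte and olfactory receptor lists at -0.21, -0.18 and -0.05 lay below theirs.

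Single promoters that differed most were Naif1 (log2 ratio 3.30) and Tmem198b (-2.19), where the strongest peak in the window was a different one in each library. At the same peak in both, the vesicle traffic gene Rab3ip had 1.06, the heparan sulfate polymerase gene Ext2 1.04, Mro 1.04 and Spata20 1.01. In the other direction, Gm21887 had -1.02, Gm45844 -0.86 and the mitotic checkpoint gene Bub3 -0.86, and Armc5 had -0.80 from different peaks. The SD of this ratio over all genes was 0.33.

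Chromosome X carried fewer and lower peaks than any autosome. It held 24.0 ± 0.174 peaks per Mb, against 60.5 ± 1.37 over the 19 autosomes, whose means ranged from 49.8 on chromosome 3 to 81.2 on chromosome 11. The ratio of X to autosomes was 0.396 ± 0.00610 per Mb and 0.604 ± 0.00929 per protein-coding gene. The median promoter signal was 1.93 ± 0.299 on X and 3.95 ± 0.295 on the autosomes (range 3.19 to 4.35), a ratio of 0.486 ± 0.0395. Of X-linked promoters 53.4% ± 0.820 were open, compared with 57.1% to 79.3% on single autosomes. The X-linked genes Alas2 and Gata1 had no promoter peak. Chromosome Y held 65 and 64 peaks, 0.703 ± 0.00771 per Mb. With the stronger 50% of the peaks the X ratio per Mb was 0.229.

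**Figure D3:**
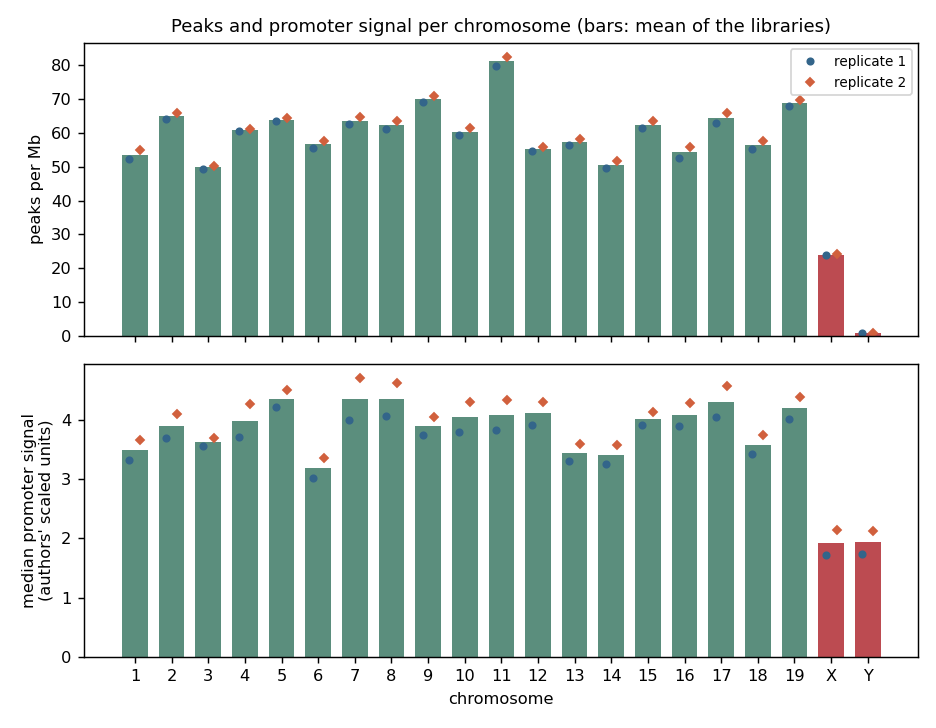
Peaks per Mb (upper panel) and median signal of the strongest promoter peak in the authors' scaled units (lower panel) for each chromosome (x axis); bars show the mean of the libraries, circles replicate 1 and diamonds replicate 2. Chromosome X lay at 24.0 peaks per Mb and a promoter signal of 1.93, below all 19 autosomes.

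Footprint calls were concentrated in strong peaks and near promoters. Of all footprints 87.6% ± 0.0329 lay in peaks. Within 1000 bp of a transcription start lay 35.5% ± 1.16 of footprints and the centres of 25.7% ± 0.735 of peaks. Among the strongest 10% of peaks 99.8% ± 0.00904 held at least 1 footprint, and among the weakest 10% the share was 39.1% ± 5.8. Promoter peaks were also the strongest by median signal. Whether footprint calls depend on the number of cuts in a peak was not tested, so these shares do not compare protein binding. Inside peaks 55.4% ± 0.519 of footprints overlapped a footprint of the other library, against 35.4% ± 0.176 for windows of the same width placed at random in the same peaks, a ratio of 1.57 ± 0.00687. Footprints of at least 20 bp were shared at 93.9% ± 0.697 and those under 10 bp at 33.3% ± 0.843. Wider windows overlap more often by chance, and no random share was drawn per width, so these 2 shares do not compare reproducibility. With a reciprocal overlap of 50%, 41.5% were shared against 12.2% at random. The promoter peaks of Peg3, Sox9, Id4 and Hes1 held footprints with NFY matches in both libraries, and Rgs9 and Rplp0 held a CTCF match. Most promoter peaks examined in this way had no word in footprints of both libraries. Across all footprints the NFY word was not called over control windows (odds ratio 1.09 ± 0.0253), so its matches at single promoters do not show binding.

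Footprints carried the binding words of CTCF, NFI, RFX and NEUROD-type E-box factors. The word of CTCF, the architectural zinc finger protein, occurred in 0.894% ± 0.0368 of footprints and 0.0118% ± 0.00584 of control windows from the same peaks (odds ratio 86.2 ± 39.5). The NFI word, bound by factors of glial and neuronal maturation, occurred in 0.373% ± 0.00777 against 0.00417% ± 0.00199 (odds ratio 101 ± 46.0). The E-box of NEUROD type, bound by proneural factors of excitatory neurons, occurred in 1.76% ± 0.103 against 0.566% ± 0.0377 (3.14 ± 0.0232). The words of KLF/SP (8.31 ± 0.462), RFX (24.5 ± 0.301), the activity-regulated EGR factors (16.2 ± 7.91), CREB and ATF (7.62 ± 1.94), YY1 (2.42 ± 0.435), the neuronal gene repressor REST (9.25 ± 3.18) and AP-1 (1.21 ± 0.0330) were also enriched by odds ratio. NRF1 matches lay in 0.0660% ± 0.00426 of footprints and in 4 and 0 control windows.

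Words of GATA and PU.1 were depleted, and those of ROR, homeodomain and POU factors only against controls not matched on G and C. The GATA word occurred in 0.0526% ± 0.0010 of footprints and 0.143% ± 0.00886 of controls (odds ratio 0.369 ± 0.0299). The word of PU.1, a myeloid factor whose gene Spi1 is in the microglia list, had an odds ratio of 0.636 ± 0.0244. Against the unmatched controls the odds ratios were 0.492 ± 0.0208 for ROR, 0.564 ± 0.0261 for DLX and LHX homeodomains and 0.601 ± 0.114 for POU factors. Fisher's exact test with Benjamini-Hochberg adjustment over 27 words called 12 higher and 5 lower in both libraries, with the largest adjusted p at ROR, 0.000892 and 0.00138. Words of MEF2, SOX, ETS, NFY, ZNF143, T-box, CUX and ONECUT, TEAD and HNF4 were not called, and HNF1 had no match in either library. Footprints were richer in G and C than controls (57.8% and 57.6%, against 52.2% and 51.7%); with controls matched on G and C, the REST, ROR, homeodomain and POU calls ended and the last 3 log2 odds ratios turned to 0.24, 0.04 and 0.30. Without extension of the footprint the AP-1 call ended, at a log2 odds ratio of -0.03.

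**Figure D4:**
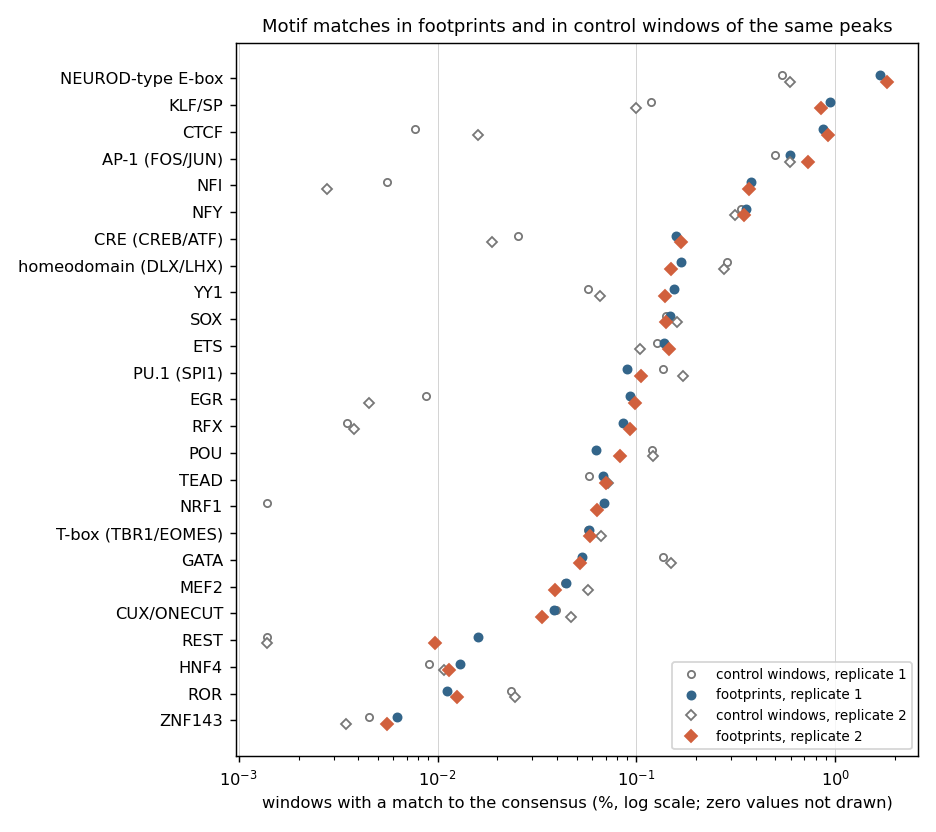
Percent of windows with a match to each consensus word (x axis, log scale; values of 0 not drawn) for reported words with any match (y axis); filled symbols show footprints, open symbols control windows of the same peaks, circles replicate 1 and diamonds replicate 2. CTCF matches lay in 0.894% of footprints and 0.0118% of control windows on average, and GATA matches in 0.0526% and 0.143%.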

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

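All alternatives were fixed before the data were examined. Over 111 results they gave 635 values, of which 544 were counted as unchanged. Apart from the ratio lists, these kept their direction and call, moved by less than the spread between libraries or, for counts, stayed within 1.5 times. With either library alone the outcome was partly fixed by construction. The genome classes, the X ratio and shared footprints of a single library always lie within that spread. A call needs both libraries, so no called list or word could be lost there. The 88 ratio list values were judged by direction and size of the shift in the median, and not by the call. The excitatory neuron list with gene body sums thus counted as unchanged at -0.067, although its percentile, 27.4, lay inside the central range. The share of peaks found in both libraries, 77.5%, was 67.6% with a reciprocal overlap of 50%, 95.6% for the stronger 50% against all peaks of the other library, 85.8% for the stronger 50% of both, and 80.3% with the stricter list. Pearson's r was 0.944 with reciprocal overlap and 0.925 for the stronger 50%. The promoter share was 19.5% with 500 bp, 34.7% with 2500 bp, 34.5% for the stronger 50% and 31.9% with the stricter list (25.2% to 26.2% in single libraries); the window sets the first pair by construction.

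The number of called promoter lists fell from 15 to 9 with CpG-matched lists, of which 8 were the same, and was 16 to 19 with either library alone. Gene body calls fell from 5 to 3 with a flank of 50 kb (5 to 6 in single libraries). Lists outside the central 95% between libraries numbered 4, and 1 with gene body sums, where the astrocyte median reversed to 0.046 and the olfactory receptor median to 0.078; the latter also reversed to 0.041 with 2500 bp and to 0.12 when centred on housekeeping genes, which raises every list by the same amount. Peaks per gene covered a median of 0.867 and 0.845 kb with a mean signal of 1.11 and 1.27 behind these sums. The X ratio of 0.396 was 0.229 for the stronger 50% (0.392 to 0.401 in single libraries). Shared footprints were 41.5% with reciprocal overlap (55.1% to 55.8% in single libraries).

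Called words numbered 17, and 17 to 21 in single libraries. Among called and uncalled words, log2 odds ratios reversed without extension to -0.034 for AP-1 and -0.26 for NFY, and with controls matched on G and C to 0.90 for MEF2, 0.24 for ROR, 0.036 for homeodomains and 0.30 for POU. Except where construction is named, the cause was not tested. The stronger 50% of footprints by score could not be run, because the score column is constant. No paired analysis was possible because there is only 1 group. Total depth is not given in the sources used here, which limits how far weak peaks listed in 1 library can be compared.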

Other observations

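The coverage of gene bodies by accessible intervals, the X promoter tests matched on CpG count, the rule that defines blocks and the test of peak height in blocks were chosen only after the result was seen.

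Activity-regulated genes had the highest share of accessible sequence in the gene body among the 25 lists. Intervals that passed the false discovery rate limit covered a median of 25.9% ± 5.77 (SD, n = 2) of the bodies of 16 activity-regulated genes, which include Fos, Arc and Npas4, against 2.41% in random lists matched on gene length. Housekeeping genes had 12.3% ± 0.281 against 2.86%, excitatory neuron genes 3.97% ± 0.0962 against 1.93%, and pan-neuronal genes 3.62% ± 0.234 against 2.06%. These 4 lists lay above the central 95% of random lists in both libraries. The random lists were not matched on CpG count, and the gene body includes the transcription start. Median gene length was 5.69 kb for activity-regulated and 9.30 kb for housekeeping genes. How much of their share came from promoter peaks was not tested. Hepatocyte (0.328% ± 0.464), germline (0.30% ± 0.0753) and lymphoid genes (0.0306% ± 0.0433) and both receptor families (0%) lay below it. Astrocyte genes had 6.39% in replicate 1 and 3.92% in replicate 2, and cortical progenitor genes 7.90% and 2.74%.

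Among the 17779 protein-coding genes of at least 5 kb, whose median coverage was 2.49% and 2.36%, 9 were covered over more than 50% in both libraries. They were Plcxd1 (75.3% ± 4.05), the orphan receptor gene Gpr85 (70.5% ± 3.36), Acap3 (69.8% ± 5.69), Il3ra (68.5% ± 19.5), Tchh (61.2% ± 6.94), the synaptic adhesion gene Slitrk1 (59.6% ± 3.72), Fam84a (58.7% ± 0.826), Marcks, which encodes an actin-binding kinase substrate (54.0% ± 0.140), and Vgf, which encodes a neuropeptide precursor (51.6% ± 0.640). The neurite growth gene Nrn1 (53.4% ± 4.99), the neuropeptide gene Adcyap1 (49.9% ± 0.790) and the potassium channel gene Kcna1 (49.9% ± 1.17) followed.

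Inhibitory neuron promoters stood higher (0.52) and excitatory neuron promoters lower (-0.21) in replicate 1. A bias by promoter CpG content is argued against, since the inhibitory list stayed at percentile 100 among lists matched on signal and CpG count, so that bias is not the whole reason. Fewer excitatory neurons, a different cell composition or striatal tissue in replicate 1 may remain: distal peaks near excitatory, inhibitory and striatal genes lay at percentiles 67.4, 94.4 and 76.4, all inside the central 95%, so these cannot be told apart from chance (the bound set in advance, percentile 50, lies within the random spread). Distal peaks near pan-neuronal (0.97), activity-regulated (1.55) and erythroid genes (1.15) lay below the central range, and those near cerebellum and hindbrain (99.6), germline (99.2) and olfactory receptor genes (98.5) above it. The labels' difference between 3 males and 1 male was not tested.

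Chromosome X had fewer and lower peaks. Promoter CpG content as the whole reason is argued against, because X promoters stood at 0.564 ± 0.0459 (SD, n = 2) of autosomal promoters matched on CpG count. A single X copy in male animals is a candidate explanation for the lower signal, with matched ratios of 0.532 and 0.597 in the libraries. It is argued against as the only reason for the low number of peaks, since X peaks above a height came to 0.454 ± 0.0152 of the autosomal peaks above 2 times that height, and 49.2% of X promoters passed that height against 55.3% of matched autosomal promoters at 2 times it. Females were not analysed here, and the biological side was not tested further.

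In 195 blocks with a median length of 7 kb, 1578 kb in all, 1 library listed more accessible sequence, mostly as weak peaks; 147 blocks overlapped a protein-coding gene. At Eif2ak1, from 143799001 to 143822000 on chromosome 5, replicate 1 listed 46 peaks and replicate 2 listed 3, and blocks lay at Dclk1 and St3gal4 for replicate 1 and at Ank3 and Gabbr1 for replicate 2. Blocks of replicate 2 starting at 37539001 and 37549001 on chromosome 9, at Nrgn, held 12 and 16 of its peaks. Replicate 1 listed 1 and 5 there. Neurod2 had a block for replicate 1 and Grin2a for replicate 2. Such peaks enter the gene body counts of the excitatory neuron list. A lower local calling threshold is a candidate explanation: 466 peaks inside the blocks that both libraries listed had a median centred log2 ratio near 0, with bootstrap bounds of -0.0364 and 0.0422. The bounds treat clustered peaks as independent and may be too narrow. A small rise over a block would change strong shared peaks little, so this ratio does not exclude raised accessibility. On average 3.78% of peaks outside were lower than the median private peak inside, 2.43% in replicate 1 and 5.14% in replicate 2. That median lay under the 5th percentile outside in replicate 1 (0.175 against 0.213) but not in replicate 2 (0.233 against 0.227). The limit set against raised accessibility was thus not met in both libraries, and the explanations cannot be told apart. The blocks held 3.80% and 2.86% of the private peaks.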
